A study of Homo sapiens with 8 samples.

How the data were processed

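Expression was measured in NTera2/D1 cells, per the labels, with siLacZ or siRNF20 and with DMSO or 10 µM RA for 72 h, as biological duplicates per the labels' growth protocol. The 8 arrays form 4 groups of 2, and each array carries the number GF117 or GF120. Per the labels' protocols total RNA was labelled with biotin by the manufacturer's protocol. The deposited values are linear intensities, one per array row and array, and how the authors corrected the background and normalized them is not given in the sources used here, nor are the tools. The upper quartile of the 7 other arrays lay between 54.9 and 55.1, against 59.8 for the GF117 RA siLacZ array. The array has no depth in counts, so that the number of arrays sets the precision. With 2 arrays against 2 the smallest two-sided exact p of a permutation test is 0.333, so that genes were tested in a model that pools the spread of all genes.

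The table of probe sets and genes identifies the rows as Affymetrix Human Exon 1.0 ST probe sets. Of 1384231 rows 369498 were listed there, 354600 with 1 gene symbol and 14898 with several, and the other 1014733 had no name and were left out, as were those with several symbols. Of 19497 symbols 16426 were current, 2950 were updated through an older symbol and 121 were kept as they were, which gave 19426 genes. Values were taken on the log2 scale with no further normalization. Rows whose mean was at or below the median row were left out as dim, and a gene's value was the median of its remaining rows in each array, for 18747 genes with 8 arrays and 18732 with 7. Genes that share sequence with a near-identical copy, such as CRIPTO with CRIPTO3 and members of the HOX and olfactory receptor families, can share signal and are uncertain to that extent. No coordinates are printed, since the sources used here state no genome build for the array; gene lengths came from the RefSeq gene table of assembly GRCh38, and 99.4% of the genes tested had one.

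limma (version 3.58.1, in R version 4.3.3 with the package data.table, version 1.17.8) fitted the means of the 4 groups to all arrays at once, with an intensity trend in the empirical Bayes step. The 5 contrasts were RA against DMSO in siLacZ and in siRNF20 cells, siRNF20 against siLacZ in DMSO and in RA, and the difference between the RA responses (siRNF20 minus siLacZ). Every adjusted p of a gene is limma's, two-sided, with Benjamini-Hochberg adjustment over the genes tested unless it is given as adjusted over the list alone, and genes were called below 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The contrasts, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Leaving out each array in turn was among them; giving the values without the GF117 RA siLacZ array first, and applying the other alternatives to those 7 arrays, was decided after its values were seen. In that fit the RA siLacZ group holds 1 array, which is assumed to vary like the others. The GF numbers were not treated as a pairing, because the labels do not say what they stand for. Deviations of arrays with one number from their group means correlated at 0.297, 0.301 and 0.364 among the groups other than RA siLacZ. The correlations with that group, which holds the GF117 RA siLacZ array, were negative. Variation shared by the arrays of one number stays in the error of the fits without a block.

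The 19 gene lists were pluripotency, HOX genes, retinoid metabolism and direct RA targets, neural progenitor, postmitotic neuron, mesoderm and endoderm, trophoblast and extraembryonic, mesenchymal and smooth muscle, epithelial, glia, H2B ubiquitylation machinery, S phase, G2 and M phase, p53 targets, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, NOTCH and WNT signalling, and reference genes. They were tested with limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 19 lists of a contrast. Beside it stand camera with the correlation estimated from the arrays, and fry. The last tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members were also adjusted over the list alone.

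Genes were named by rule: RNF20, RNF40 and USP44 always; in each pairwise contrast the 8 highest and 8 lowest log2 changes among the genes called whose sign was the same in GF117 and GF120; in the difference between responses the 6 highest and 6 lowest; with none called, the 4 highest and 4 lowest, given as not passing; and in each list up to 4 members with the largest change. With 7 arrays the RA siLacZ comparisons have a sign in GF120 alone. Further members, named where few of a list were called, and POU5F1 and SOX2 were chosen after their values were seen.

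The share of the RA response kept was the ratio of the median responses of siRNF20 and siLacZ cells in one GF number over 200 genes per side selected in the other, with no test. Gene length was set against the difference between responses by Spearman's rho across genes, with a two-sided permutation of genes (100000 resamples for the main relations, 10000 for the relations over all genes), over genes raised at least 2-fold or, where fewer than 50 were called, the 200 most raised. There were 22 such relations in the family, adjusted together. A correlation or ratio with no spread between replicates was taken as unmoved when an alternative changed it by less than 0.1. Expected overlaps are those of independent lists of the same sizes among the genes tested.

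Alternatives were the mean over rows, no filter and a stricter filter on dim rows (the upper quartile), quantile normalization, centring on the median, an offset of 16 before the logarithm, no intensity trend, the GF number as a block, a fit on the arrays of the groups compared and leaving out each array. The steps were tested on simulated data with 200 of 18732 genes changed, in 5 simulations. With 7 arrays the test recovered 24.0% of 2-fold and 92.4% of 4-fold changes for RA in siLacZ cells, 51.2% and 97.8% for RA in siRNF20 cells, 46.0% and 98.4% for siRNF20 in DMSO, 28.6% and 90.6% for siRNF20 in RA, and 7.00% and 66.8% for the difference between responses. Between 6.35% and 9.56% of the calls were false. These shares hold for 200 changed genes in each run, and fewer changed genes make the adjustment stricter. RNF20 itself, at -1.94 with siRNF20 in DMSO, was not called in the real data. With the GF117 RA siLacZ array as deposited the simulated changes gave 0 calls. A pluripotency list of 33 genes shifted by -0.5 was found in 20 of 20 simulations, in 15 with an estimated correlation, and other lists in 2 of 360 tests. The simulated genes were drawn independently of one another, so that these runs cannot test the preset correlation between genes. A relation with gene length simulated at rho = 0.3 in 336 genes was found at 0.274, 1 of 40 runs with no relation passed, and a share of 0.75 was found at 0.720 (raised) and 0.716 (lowered). Rows without a name or with several, and genes of the sex chromosomes that could tell a donor's sex, were left out of the text.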

Results

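Gene expression was measured on Affymetrix exon arrays in NTera2/D1 cells, a human embryonal carcinoma line that retinoic acid (RA) drives out of its stem-cell-like state. The cells received a small interfering RNA against RNF20 (siRNF20) or against the bacterial gene LacZ as the control (siLacZ). RNF20 is an E3 ligase that attaches a single ubiquitin to histone H2B. DMSO, the solvent, or 10 µM RA was then given for 72 h. The 4 groups held 2 arrays each, numbered GF117 and GF120. The design asks which genes RA changes, which genes the loss of RNF20 changes, and whether the response to RA differs when RNF20 is depleted. Each array held 1384231 values with a median intensity of 17.2 on 7 arrays and 18.4 on the GF117 RA siLacZ array, and the number of arrays limits the precision of every comparison.

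The GF117 array of the RA-treated siLacZ cells stood apart from the others. Its gene values correlated at Pearson r = 0.0780 to 0.185 with the 7 other arrays, which correlated with one another at 0.908 to 0.974. Reference genes such as those of the ribosome and of glycolysis, which most cells express strongly, had a median log2 intensity of 6.94 on this array and of 9.98 to 10.33 on the others. Differences between genes made up a share of 0.204 of the variance between its annotated array rows, against 0.486 to 0.544 elsewhere. The marker H19 still stood at 10.86 on it and the RA-degrading enzyme gene CYP26A1 at 8.33. With all 8 arrays, as planned, limma called 0 genes in each of the 5 comparisons. Values from the 7 other arrays, which leave the GF120 array alone in the RA siLacZ group, are therefore given first below, with those of all 8 beside them; that order was chosen after the values were seen. The lone array carries GF120 and is set against arrays of both numbers, so that differences between the numbers enter its comparisons in part. Within GF120 alone the medians of lists with RA in siLacZ cells were -0.914 (pluripotency), 1.66 (retinoid metabolism and direct RA targets) and -0.112 (cholesterol synthesis). These are smaller in size than those of 7 arrays below, while that of HOX genes (0.488) was larger. The lone array is also assumed to vary like the arrays of the other groups. Had the GF120 array been left out in its place, 13323 genes would have passed for RA in siLacZ cells, 721 for RA in siRNF20 cells, 12835 for siRNF20 in RA and 11416 for the difference between the RA responses.

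**Figure D1:**
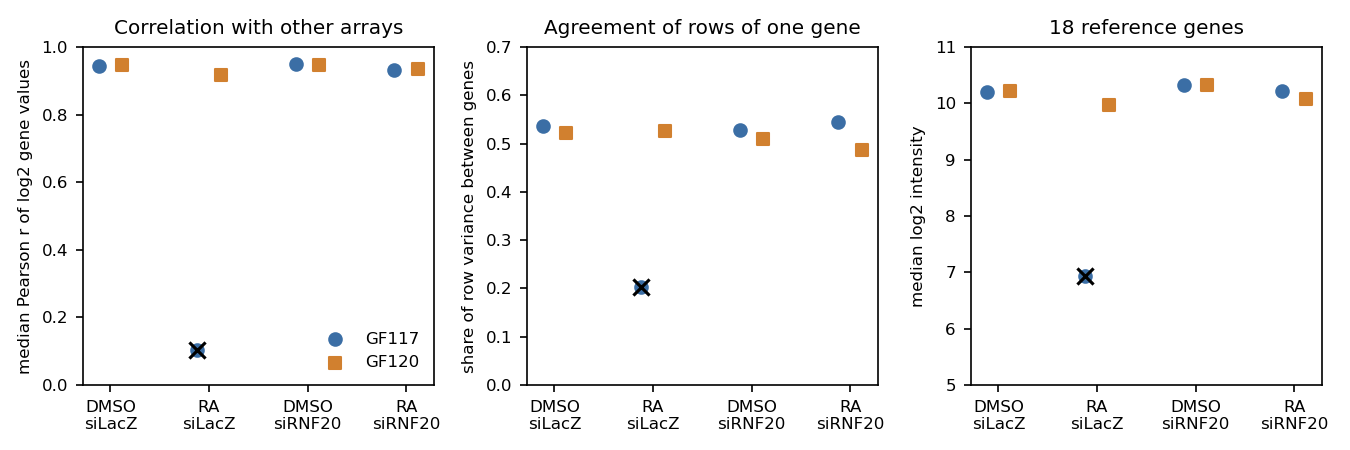
Agreement of each array with the others as the median Pearson correlation over genes (left), the share of the variance between array rows that lies between genes (middle) and the median log2 intensity of 18 reference genes (right), by group; circles are GF117, squares GF120 and the cross the GF117 RA siLacZ array. That array lies at 0.103, 0.204 and 6.94 and below every other array in all panels.

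RNF20 itself was lower in each of the 4 siRNF20 arrays than in each siLacZ array other than the GF117 RA siLacZ array. Its log2 intensity was 8.24 and 8.09 in the DMSO siLacZ arrays and 8.10 in the GF120 RA siLacZ array, against 6.48, 5.98, 6.27 and 5.89 in the siRNF20 arrays. The log2 difference was -1.94 (SE 0.23, n = 2 and 2) in DMSO and -2.02 (SE 0.29, n = 2 and 1) in RA. Over all 18732 genes these differences had an adjusted p of 0.237 and 0.110, and adjusted over the list alone, the machinery of H2B ubiquitylation, 0.000354 and 0.00131. The GF117 RA siLacZ array read 6.08 for RNF20, so that with all 8 arrays the difference in RA was -1.01 (SE 0.68) and within GF117 it was 0.19. The fits in this paragraph leave out the GF number as a block. With that block RNF20 passed over all genes in DMSO and in RA, as given in the last part. RNF40, the partner that forms the ligase with RNF20, differed by 0.02 (SE 0.19) in DMSO and 0.12 (SE 0.23) in RA. The sign of the RNF40 values turned without the GF120 DMSO siLacZ array (-0.07 in DMSO) and without the GF117 RA siRNF20 array (-0.01 in RA). For RA it also turned with the mean over rows (-0.11) and a stricter filter on dim rows (-0.09).

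USP44, a deubiquitylase that removes ubiquitin from histone H2B, fell with RA. The decrease was 1.22 on the log2 scale in siLacZ cells (log2 -1.22, SE 0.27, adjusted p = 0.0374, n = 1 and 2) and 1.11 in siRNF20 cells (log2 -1.11, SE 0.22, adjusted p = 0.0229, n = 2 and 2). siRNF20 itself gave a USP44 difference of 0.27 in DMSO and 0.39 in RA, neither past the threshold. No other member of the 28 measured in the H2B ubiquitylation list was called under RA in either background (adjusted p of the list 0.678 and 0.996). The call in siLacZ cells was lost without the GF117 DMSO siLacZ array (-1.05, adjusted p = 0.185) and without the GF120 one (-1.40, adjusted p = 0.0694). In siRNF20 cells it was lost without the GF117 DMSO siRNF20 array (-0.94, adjusted p = 0.177) and without the GF120 RA siRNF20 array (-0.80, adjusted p = 0.0840). With all 8 arrays the USP44 differences were -3.40 (SE 1.33), -1.11, 0.27 and 2.56 in the same order, none past the threshold.

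**Figure D2:**
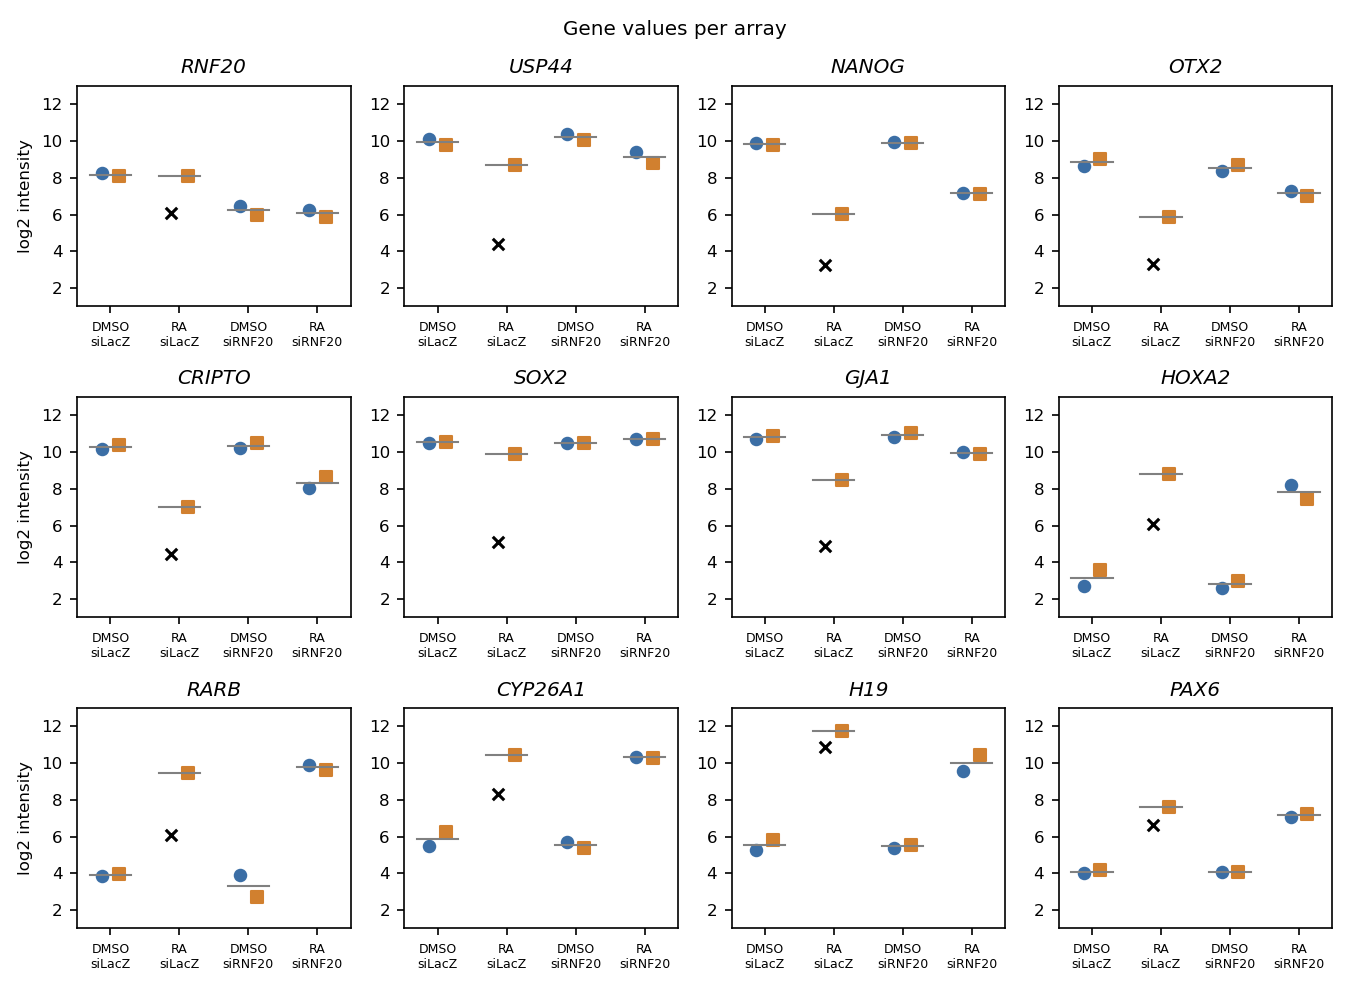
Log2 intensity of 12 genes on each array, by group; circles are GF117, squares GF120, crosses the GF117 RA siLacZ array, and the grey line is the group mean without it. RNF20 lay between 5.89 and 6.48 in the siRNF20 arrays, and NANOG was lower with RA on every array.

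RA lowered pluripotency genes and raised HOX genes and genes of the retinoid response in the control cells. In siLacZ cells H19, an imprinted long non-coding RNA, rose most, by 6.20 on the log2 scale or 73.6-fold (SE 0.35, adjusted p = 8.33e-05, n = 1 RA and 2 DMSO arrays). SKAP2, a neighbour of the HOXA cluster, rose by 5.85 (SE 0.29), HOXA2, which patterns the hindbrain, by 5.68 (SE 0.46) and the retinoic acid receptor gene RARB by 5.55 (SE 0.43). NANOG, a core pluripotency factor, fell by 3.82 (SE 0.19, adjusted p = 4.36e-05), and CRIPTO, a NODAL co-receptor of stem cells, fell by 3.26 (SE 0.26). In all, 733 of 18732 genes changed, 352 higher and 381 lower, of which 661 changed at least 2-fold. The others among the largest increases were FLJ12825 (5.83), SLITRK6 (5.55), the carotene-cleaving enzyme gene BCO1 (5.46) and MIR99AHG (5.07). The others among the largest decreases were MAS1 (-4.82, from 1 row), D21S2088E (-4.11), GRPR, a receptor for gastrin-releasing peptide (-3.47), the transcription factor gene ETS1 (-3.43), SLC46A3 (-3.32) and CKMT1A (-3.24). Among these increases, the DMSO values of HOXA2, RARB, FLJ12825, SLITRK6, BCO1 and MIR99AHG lay below the median intensity of the arrays. Among the decreases, the RA values of MAS1, D21S2088E, ETS1, SLC46A3 and CKMT1A lay below it. The size and order of these changes depend on how dim values are treated. ETS1 stood at -2.52 in the alternative with the smallest change. With an offset of 16 before the logarithm H19 rose by 5.78, SKAP2 by 4.96, RARB by 4.49, FLJ12825 by 4.25, BCO1 by 4.18, HOXA2 by 3.60, MIR99AHG by 3.32 and SLITRK6 by 2.74, all past the threshold. HOXA2 rose by 2.38 with a stricter filter on dim rows, MIR99AHG by 2.43 in a fit on the 3 siLacZ arrays, and MAS1 fell by 1.77 without the filter.

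Of 33 measured pluripotency genes in siLacZ cells, 16 fell, 2 rose and 15 did not pass (median -1.03, adjusted p of the list 1.13e-13). Adjusted over the list alone, 20 fell and 2 rose. OTX2 fell by 2.99 (SE 0.25) and POLR3G by 2.83, and the calls reached POU5F1 (-1.83) and SOX2 (-0.62), which were chosen for mention after their values were seen. The exceptions were LEFTY2 (3.44, SE 0.24) and LEFTY1 (2.85), secreted inhibitors of NODAL, which rose. Among 36 HOX genes 11 rose, 0 fell and 25 did not pass (adjusted p = 1.36e-07), with HOXA5 at 4.73, HOXB2 at 4.65 and HOXD3 at 4.41; adjusted over the list alone, 16 rose and 2 fell. Of 26 genes of retinoid metabolism and direct RA targets, 14 rose, 2 fell (RET and ALDH1A3) and 10 did not pass (median 1.72, adjusted p = 2.5e-16). MEIS2, a cofactor of HOX proteins, rose by 4.99 (SE 0.38) and CYP26A1 by 4.59 (SE 0.31), and adjusted over the list alone 16 rose and 2 fell. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0287, 0.0467 and 0.0287).

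Neural genes moved in part. In the neural progenitor list 4 of 29 rose in siLacZ cells (PAX6 by 3.54, CDH2 by 2.40, IRX3 and MSI1) and OLIG3 fell, with an adjusted p of 0.0176 for the list, or adjusted p = 0.234 with an estimated correlation. Of 37 genes of postmitotic neurons 4 rose (the axon guidance receptor gene ROBO2 by 4.85, DCX by 2.55, NCAM1 by 2.04 and ISL1) and DPYSL3 fell. This list had an adjusted p of 0.0391, or adjusted p = 0.572 with an estimated correlation, and the call was lost without the GF120 DMSO siLacZ array (adjusted p = 0.237). Adjusted over the list alone, 7 neural progenitor genes rose and 2 fell, and 5 neuron genes rose and 1 fell. Of 19 cholesterol synthesis genes 2 fell (HMGCS1 and CYP51A1; 5 adjusted over the list alone), and the list's median was -0.40 (adjusted p = 0.000784, or adjusted p = 0.612 with an estimated correlation). Of 27 genes of ATF4 and the unfolded protein response 4 fell (MTHFD2 by 1.49, ASNS, XBP1 and HSPA5) and VLDLR rose by 1.57 (adjusted p = 0.0197, or adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone, 5 of these fell and 1 rose; without the GF120 DMSO siLacZ array the list had an adjusted p of 0.115.

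The other lists did not pass as lists in siLacZ cells, although single members did. KDR, the main VEGF receptor, fell by 3.05 and PDGFRA rose by 2.65 among 26 mesoderm and endoderm genes (adjusted p = 0.367). TFAP2A rose among 15 trophoblast genes (adjusted p = 0.410), and ACTA2, COL5A2 and COL1A1 rose and THY1 fell among 24 mesenchymal genes (adjusted p = 0.793). EPCAM (-2.06), ESRP1 (-1.62) and MAL2 fell among 17 epithelial genes (adjusted p = 0.145), and the gap junction gene GJA1 (-2.36, SE 0.16) and ERBB3 among 11 glial genes (adjusted p = 0.0920). The 29 S phase genes (PCNA and RFC4 fell) had an adjusted p of 0.0785, the 31 G2 and M phase genes (PTTG1 rose) 0.919, and the 28 p53 targets (TP53INP1 and BTG2 rose) 0.0558. PMAIP1, also a p53 target, went the other way, at a log2 intensity of 6.2 on the GF120 RA siLacZ array and 9.1 on both DMSO siLacZ arrays. The 28 interferon response genes (0 called) had an adjusted p of 0.792, the 34 NOTCH and WNT genes (FZD5 fell) 0.678, and the 18 reference genes (B2M fell) 0.410.

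The count for RA in siLacZ cells depends on each control array: 317 genes passed without the GF117 DMSO siLacZ array and 389 without the GF120 one. Leaving out one or other of them ended the calls of CKMT1A, D21S2088E, POU5F1, SOX2, RET, ALDH1A3, OLIG3, IRX3, MSI1, ISL1, DPYSL3, TFAP2A, ACTA2, COL5A2, COL1A1, THY1, MAL2, ERBB3, PCNA, RFC4, PTTG1, BTG2, ASNS, XBP1, HMGCS1, CYP51A1, FZD5 and B2M (adjusted p from 0.0574 to 0.225), and leaving out a DMSO siRNF20 array ended those of TFAP2A, SOX2, COL1A1, ACTA2, ERBB3, B2M, CYP51A1, MSI1 and XBP1 (adjusted p from 0.0503 to 0.0995). SLC46A3 rests on 1 array row and stood at 0.10 without the filter on dim rows, and an offset of 16 before the logarithm ended the calls of D21S2088E (-1.97) and CKMT1A (-1.54). With the mean over rows PTTG1 went from 1.42 to 0.31, PCNA from -1.01 to -0.50, RFC4 from -0.92 to -0.56, B2M from -1.06 to -0.62 and ACTA2 from 1.71 to 1.08, and with a stricter filter PTTG1 stood at 0.47 and TFAP2A went from 1.44 to 0.64, each without a call (adjusted p from 0.0624 to 0.443). The mean also ended the calls of TFAP2A, XBP1, CYP51A1, D21S2088E, FZD5 and ASNS, and the stricter filter those of ACTA2, PCNA, OLIG3, CYP51A1, RET and SOX2. Without the intensity trend further calls ended, among them that of HSPA5 (-0.80) and, with RA in siRNF20 cells, that of GJA1 (-0.96). With all 8 arrays limma called 0 genes (1510 at an unadjusted p under 0.05, smallest adjusted p 0.131). The median of all genes was then -0.49, and H19 (5.76), FLJ12825 (4.47), LOC100129455 (4.07), HOXA2 (4.02), CRIPTO3 (-5.47), NANOG (-5.20), L1TD1 (-4.57) and CRIPTO (-4.54) had the largest differences.

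siRNF20 cells given RA raised HOX and retinoid genes and lowered pluripotency genes as well. SKAP2 rose by 6.48 (SE 0.23, adjusted p = 4.48e-06, n = 2 and 2) and RARB by 6.46 (SE 0.35, adjusted p = 3.14e-05). HOXA5 rose by 5.79 (SE 0.36), MEIS2 by 5.24 (SE 0.31), HOXA2 by 5.06 (SE 0.37), CYP26A1 by 4.77 (SE 0.25) and LOC100129455 by 4.70 (SE 0.36). SEMA3C, which encodes a secreted guidance cue, rose as well, by 3.45 with an offset of 16. Among these, the DMSO values of SKAP2, RARB, HOXA5, HOXA2, LOC100129455 and SEMA3C lay below the median intensity of the arrays, so that their sizes depend on how dim values are treated. With the offset the first 5 rose by 5.40, 5.03, 3.87, 3.02 and 2.86, and with a stricter filter HOXA5 rose by 2.35 and HOXA2 by 1.90. The largest decreases were those of GRPR (-4.23, SE 0.30), VSNL1 (-3.57), KDR (-3.39), D21S2088E (-3.37), ETS1 (-3.24), the p53 target PMAIP1 (-3.24), CHST4 (-3.22) and the complement receptor gene CR2 (-3.03). The RA values of GRPR, VSNL1, KDR and D21S2088E lay below the median intensity of the arrays, as did that of ETS1 in GF120. The size and order of these decreases are uncertain to that extent. In the alternative with the smallest change GRPR stood at -3.10, VSNL1 at -2.46, KDR at -2.46, ETS1 at -2.37 and D21S2088E at -1.81. A total of 734 genes changed, 335 higher and 399 lower, of which 579 changed at least 2-fold.

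Of the 33 pluripotency genes 16 fell, 2 rose and 15 did not pass in siRNF20 cells (median -0.89, adjusted p = 1.74e-11). NANOG fell by 2.76 (SE 0.16), DPPA2 by 2.73 (SE 0.26) and POLR3G by 2.61, while LEFTY2 rose by 3.74 (SE 0.19) and LEFTY1 by 2.48. Among genes chosen after their values were seen, POU5F1 fell by 2.46 and SOX2 stood at 0.22 (adjusted p = 0.389). Adjusted over the list alone, 19 fell and 3 rose. Of 36 HOX genes 12 rose (HOXB2 by 4.70, HOXD3 by 4.01), 2 of the posterior HOXD genes fell (HOXD11 and HOXD13) and 22 did not pass (adjusted p = 1.53e-07); adjusted over the list alone, 12 rose and 3 fell. In the retinoid list 15 of 26 rose, RET and ALDH1A3 fell and 9 did not pass (median 1.21, adjusted p = 9.79e-20), with 17 and 2 adjusted over the list alone. These 3 lists again kept their calls with an estimated correlation (adjusted p = 0.0374, 0.0472 and 0.0348). In the neural progenitor list PAX6 (3.08), CDH2 (1.44), SOX3 (1.13) and NES rose and OLIG3 fell (adjusted p = 0.00104, or adjusted p = 0.128 with an estimated correlation; adjusted over the list alone, 8 rose and 1 fell).

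Further lists passed in siRNF20 cells with the preset correlation alone. GATA3, IGFBP3 and TFAP2A (2.47, SE 0.24) rose among 15 trophoblast genes (adjusted p = 0.0313, or adjusted p = 0.341 with an estimated correlation), and the same 3 passed adjusted over the list alone. This list did not pass without the GF117 DMSO siRNF20 array (adjusted p = 0.111) or the GF120 RA siRNF20 array (0.0856). ESRP1 (-1.28), EPCAM (-1.19) and MAL2 fell among 17 epithelial genes (adjusted p = 0.0368, or adjusted p = 0.697 with an estimated correlation; adjusted over the list alone, 5 fell and 1 rose). TP53INP1 (1.68) and BTG2 (1.85) rose among 28 p53 targets (adjusted p = 0.0423, or adjusted p = 0.821 with an estimated correlation; 3 adjusted over the list alone). PMAIP1, also a p53 target, went the other way in these cells, as given above among the largest decreases. Without the GF117 RA siRNF20 array the epithelial and p53 lists had adjusted p values of 0.454 and 0.262, and without the GF120 DMSO siRNF20 array 0.442 and 0.460. CHAC1, ASNS (-1.10) and MTHFD2 (-0.98) fell and VLDLR rose (1.21) among 27 ATF4 and unfolded protein response genes (adjusted p = 0.0008, or adjusted p = 0.341 with an estimated correlation; adjusted over the list alone, 10 fell and 1 rose). DHCR7 fell among 19 cholesterol synthesis genes (adjusted p = 0.0008, or adjusted p = 0.692 with an estimated correlation; 1 adjusted over the list alone).

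In the neuron list of siRNF20 cells ROBO2 (4.62), ISL1, NCAM1 (1.66), DCX (1.55) and MAP2 rose and DPYSL3 and L1CAM fell; its median was -0.06, its mean 0.14 and its adjusted p 0.552. PDGFRA rose and KDR fell among mesoderm and endoderm genes (adjusted p = 0.800), COL5A2 rose and THY1 fell among mesenchymal genes (0.800), and GJA1 (-0.96) and ERBB3 fell among glial genes (0.0592). FZD7 rose (1.44) and FZD5 (-1.54), SFRP2 (-1.50) and SFRP1 fell among NOTCH and WNT genes (0.971), and TFRC fell among reference genes (0.996). The S phase, G2 and M phase and interferon lists had 0 members called and adjusted p values of 0.552, 0.607 and 0.797.

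For siRNF20 cells the count fell to 324 without the GF117 DMSO siRNF20 array and to 371 without the GF120 one. Leaving out 1 of the 4 siRNF20 arrays ended, in at least 1 case, the calls of VSNL1, D21S2088E, PDGFRA, OTX2, SOX3, NES, OLIG3, IGFBP3, GATA3, EPCAM, MAL2, RET, ALDH1A3, HOXB13, HOXD11, HOXD13, COL5A2, MAP2, L1CAM, DPYSL3, CHAC1, ASNS, DHCR7, SFRP1 and TFRC (adjusted p from 0.0503 to 0.41), and leaving out a DMSO siLacZ array ended those of D21S2088E, IGFBP3, DHCR7, COL5A2, SFRP1 and NES (adjusted p from 0.0512 to 0.084). A stricter filter on dim rows ended the calls of TFAP2A (from 2.47 to 1.19), GATA3 (from 1.55 to 0.51), CHAC1 (from -1.20 to -0.26), HOXD11, L1CAM, IGFBP3, DHCR7 and SFRP1 (adjusted p from 0.0508 to 0.72). With all 8 arrays limma called 0 genes (504 at an unadjusted p under 0.05, smallest adjusted p 0.202), and a fit on the 4 siRNF20 arrays alone called 549, of which 269 were higher. In the fit of all 8 arrays SKAP2 (6.48), RARB (6.46), HOXA5 (6.38), MEIS2 (5.24), GRPR (-4.23), D21S2088E (-3.74), VSNL1 (-3.57) and KDR (-3.40) had the largest differences, none past the threshold.

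The RA responses of the 2 backgrounds overlapped widely. Of the genes raised in siLacZ cells, 245 were also raised in siRNF20 cells, where 6.30 would be shared by independent lists of these sizes, and 193 were lowered in both, against 8.12. SKAP2, RARB, HOXA2, HOXB2, HOXD3, MEIS2 and CYP26A1 rose in both, NANOG, GRPR, ETS1 and KDR fell in both, and 0 genes were called in opposite directions. Of the siLacZ calls 348 of 352 raised genes and 355 of 381 lowered genes had the same sign in siRNF20 cells. Across genes, which are not independent replicates, the responses correlated at Pearson r = 0.699 and Spearman rho = 0.513; with all 8 arrays the values were 0.353 and 0.268, and within GF120 Pearson r was 0.582. For the 200 genes raised most in the GF117 siRNF20 arrays, the median response in GF120 was 1.76 in siRNF20 cells and 2.18 in siLacZ cells, a ratio of 0.809. For the 200 lowered most it was -1.44 and -1.24, a ratio of 1.17. This selection, which avoids the GF117 RA siLacZ array, was added after the values were seen. It favours genes that respond more in siRNF20 cells, so that 1.17 does not show a stronger lowering there. With pluripotency genes left aside, the median difference between responses in GF120 was -0.0862 over 200 lowered genes so selected. Selected in the GF120 siLacZ arrays, which favours the opposite, it was 0.700. The planned selections use the GF117 RA siLacZ array. From siLacZ GF117 they gave ratios of 0.850 (raised) and 1.15 (lowered), and from siLacZ GF120 ratios of 4.73 and 0.441. The medians behind 0.850 were only 0.0769 in siRNF20 and 0.0904 in siLacZ cells, and those behind 1.15 were -0.228 and -0.199. Ratios of medians so small say little about the share kept. The ratios from siLacZ GF120 were measured in GF117, on that array itself.

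**Figure D3:**
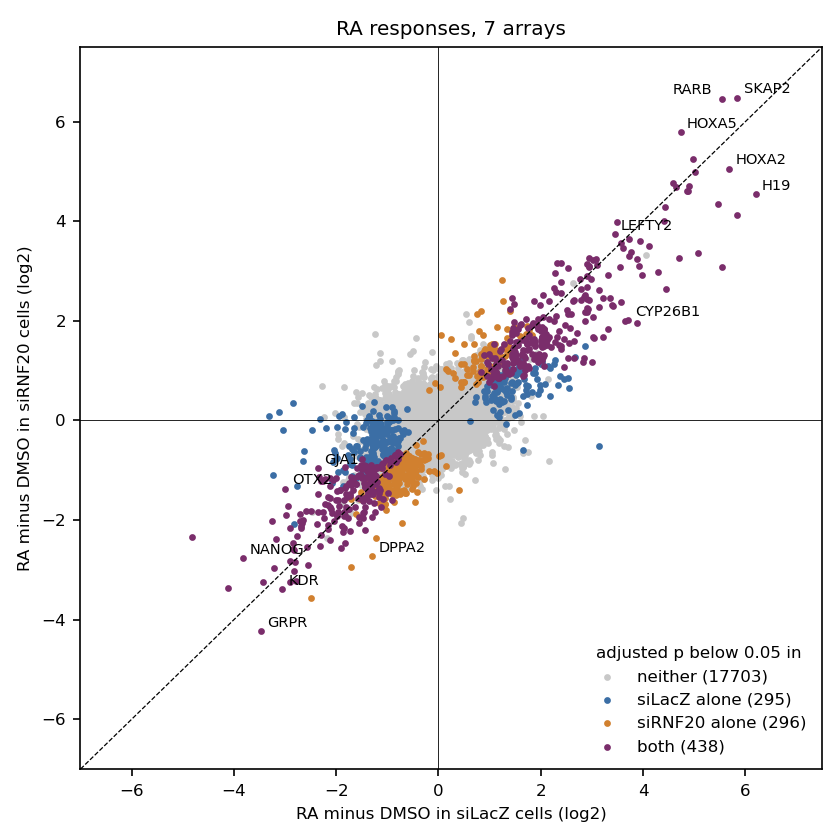
Log2 change with RA in siLacZ cells (x axis) and siRNF20 cells (y axis) for each gene, from 7 arrays, coloured by where it was called; the dashed line marks equal responses. 438 genes were called in both, 295 in siLacZ cells alone and 296 in siRNF20 cells alone, with 0 called in opposite directions.

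Depletion of RNF20 in DMSO gave no called gene in the fit without the GF number as a block. With that block RNF20 itself passed. Small shifts of gene groups passed with the preset correlation alone. limma called 0 genes for siRNF20 in DMSO with 7 arrays (519 at an unadjusted p under 0.05, smallest adjusted p 0.237) and 0 with 8 (27, smallest 1.00). Without the GF117 DMSO siRNF20 array 1 gene passed, the peroxiredoxin gene PRDX2 (3.05, SE 0.32, adjusted p = 0.0487). RNF20 (-1.94) had the largest decrease that went the same way in GF117 and GF120, followed by TSPYL5 (-1.75), the histone gene HIST1H2BG (-1.59) and KRTAP21-1 (-1.55), and EPCIP-AS1 (2.60), ATP6V1G3 (1.80), LOC646652 (1.60) and PCDHGA12 (1.58) the largest increases; apart from RNF20 none passed any adjustment. EPCIP-AS1 turned to -1.06 in a fit on the 4 DMSO arrays, and ATP6V1G3 (-0.22) and TSPYL5 (0.47) turned without the filter on dim rows. Adjusted over the list alone, RNF20 and the NOTCH ligand gene DLL1 (-0.89, SE 0.20, adjusted p = 0.0365), in the neural progenitor list, passed. With 8 arrays OR4X1 (2.04), ENKUR (1.88), S100A7 (-2.99), TEKT5 (-2.31) and HOXA5 (-1.97) joined the largest, none past the threshold, and TEKT5 and HOXA5 turned direction under other settings.

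The p53 targets were lower with siRNF20 in DMSO as a group, with 22 of 28 negative and a median of -0.27 (adjusted p = 8.48e-05, or adjusted p = 0.467 with an estimated correlation). The stress cytokine gene GDF15 stood at -0.66, the cell cycle inhibitor gene CDKN1A at -0.59 and ZMAT3 at -0.56; CDKN1A turned to 0.27 with a stricter filter. Cholesterol synthesis genes were higher in 15 of 19 (median 0.17, DHCR7 at 0.47 and MSMO1 at 0.43; adjusted p = 0.0011, or adjusted p = 0.505 with an estimated correlation). ATF4 and unfolded protein response genes were higher in 20 of 27 (median 0.17, the amino acid transporter gene SLC7A5 at 0.58; adjusted p = 0.00185, or adjusted p = 0.467 with an estimated correlation). Genes of postmitotic neurons were higher in 24 of 37 (median 0.22, SYT4 at 1.16; adjusted p = 0.00261, or adjusted p = 0.467 with an estimated correlation). In these 4 lists 0 members passed over all genes or adjusted over the list alone, and no list in this comparison held with an estimated correlation. The p53 call was lost without the GF120 DMSO siRNF20 array (adjusted p = 0.155) and the neuron call without the GF120 DMSO siLacZ array (0.513). Cholesterol synthesis lost its call without the GF117 DMSO siRNF20 array (0.175) or the GF120 DMSO siLacZ array (0.640), and the ATF4 list without the GF117 DMSO siLacZ array (0.0884) or the GF117 DMSO siRNF20 array (0.115). The other 15 lists did not pass, with pluripotency at a median of 0.05 (adjusted p = 0.110), HOX genes at -0.01 (0.978), the retinoid list at -0.07 (0.130) and G2 and M phase at -0.11 (0.0532).

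In RA-treated cells GJA1, and pluripotency genes as a list, were higher with siRNF20 than with siLacZ. The list passed with the preset correlation, and neither with an estimated correlation nor with fry. The calls in this paragraph come from fits without the GF number as a block. With that block more genes passed over all genes, NANOG, SOX2, OTX2 and CRIPTO among them. The last part gives their count alone. GJA1 was higher by 1.51 (SE 0.16) and CCDC190, from 1 array row, by 3.35 (SE 0.36), each with an adjusted p of 0.0474 and n = 2 and 1. These were the 2 genes called, with 1485 at an unadjusted p under 0.05. Both calls were lost when any 1 of the 6 arrays that leave each group an array was left out (adjusted p from 0.0595 to 0.181), and CCDC190 stood at 0.76 without the filter on dim rows. Without the GF120 RA siRNF20 array the 2 genes called were others, HAS2 (2.84, SE 0.29) and SCARNA7 (SE 0.22), both higher, each with an adjusted p of 0.0434. A fit on the RA arrays alone called 48 genes but neither of these 2 (GJA1 at 0.96, adjusted p = 0.0529; CCDC190 at 1.28, adjusted p = 0.473), and 0 passed with the mean over rows, another filter on dim rows, quantile normalization or an offset of 16. Of 33 pluripotency genes 26 were positive (median 0.20, adjusted p = 0.000108, or adjusted p = 0.261 with an estimated correlation). Over all genes 0 members passed and adjusted over the list alone 7 did, all higher, among them NANOG (1.15, adjusted p = 0.00279), SOX2 (0.81, 0.00279), OTX2 (1.32, 0.00478) and CRIPTO (1.31, 0.00478).

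Other groups also shifted between the RA-treated cells. Cholesterol synthesis genes were positive in 15 of 19 (median 0.19, adjusted p = 0.00482, or adjusted p = 0.604 with an estimated correlation), with 3 past the threshold adjusted over the list alone, HMGCS1 (1.31) and MSMO1 (0.96) among them. S phase genes were positive in 22 of 29 (median 0.11, adjusted p = 0.0117, or adjusted p = 0.604 with an estimated correlation), and adjusted over the list alone PCNA, the replication clamp (1.31, adjusted p = 0.00617), and RFC4 (0.86, 0.0195) passed. The p53 targets were negative in 22 of 28 (median -0.27, adjusted p = 0.00796, or adjusted p = 0.604 with an estimated correlation) and G2 and M phase genes in 23 of 31 (median -0.17, adjusted p = 0.0316, or adjusted p = 0.724 with an estimated correlation); 0 of their members passed adjusted over the list alone. Leaving out the GF120 RA siRNF20 array ended the p53 call (0.104) and turned the direction of the G2 and M phase list (0.809), and leaving out the GF117 RA siRNF20 array ended the S phase call (0.0551). In lists that did not pass, EPCAM (1.22), VIM (1.20) and B2M (1.31) were higher and the RA-degrading enzyme gene CYP26B1 (-1.95) and NR2F2 (-1.07) lower, each adjusted over the list alone. The retinoid list had a median of 0.09, a mean of -0.11 and an adjusted p of 0.471, and no list in this comparison held with an estimated correlation. With all 8 arrays limma called 0 genes (560 at an unadjusted p under 0.05, smallest adjusted p 0.546) and the median of all genes was 0.43. HAS2 (4.22), B3GNT2 (3.73), TSPAN6 (3.73), ARF4 (3.57) and the genes OR8D1 (-4.99), OR4D11 (-4.38), OR5P2 (-4.07) and FLJ40288 (-3.83) then lay farthest out, with OR5P2 at 0.39 without the filter on dim rows.

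In the fit without the GF number as a block, no single gene's RA response differed between the backgrounds past the threshold over all genes. With that block some genes did, GJA1 among them, as given in the last part. The test of the difference, siRNF20 minus siLacZ, called 0 genes in limma with 7 arrays (737 at an unadjusted p under 0.05, smallest adjusted p 0.453) and 0 with 8 (113, smallest 0.794, median of all genes 0.46). Pluripotency genes nonetheless stood higher as a group, with 24 of 33 positive and a median difference of 0.22 (adjusted p = 0.0119, or adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone, OTX2 (1.62, SE 0.33, adjusted p = 0.0132), SOX2 (0.84, SE 0.17, 0.0132), NANOG (1.06, SE 0.25, 0.0189) and CRIPTO (1.24, SE 0.33, 0.0375) were higher and DPPA2 (-1.44, SE 0.40, 0.0376) lower. SOX2 thus stood at -0.62 with RA in siLacZ cells and 0.22 in siRNF20 cells, and OTX2 at -2.99 and -1.37. The pluripotency list as a whole did not pass with fry. GJA1 differed by 1.40 (SE 0.21, adjusted p = 0.000798), adjusted over the list alone, the glial list. The list call was lost without the GF117 DMSO siRNF20 array (adjusted p = 0.308) and without the GF120 RA siRNF20 array (0.191). The other 18 lists did not pass; the retinoid list had a median of 0.14 and a mean of -0.03 (adjusted p = 0.935), HOX genes a median of -0.08 (0.498) and genes of postmitotic neurons of -0.14 (0.232). The largest differences with the same sign in GF120, none past the threshold, were those of SLC46A3 (3.41), LOC644634 (3.29), CCDC190 (3.21), LOC643014 (2.98), EPCIP-AS1 (-3.66), FCER1A (-2.99), SPIC (-2.51) and SLITRK6 (-2.48). With 8 arrays they were TSPAN6 (3.69), B3GNT2 (3.69), ARF4 (3.58), SCARNA9 (3.57), OR8D1 (-4.34), OR6K6 (-4.19), SPAG11B (-3.73) and ENKUR (-3.51).

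**Figure D4:**
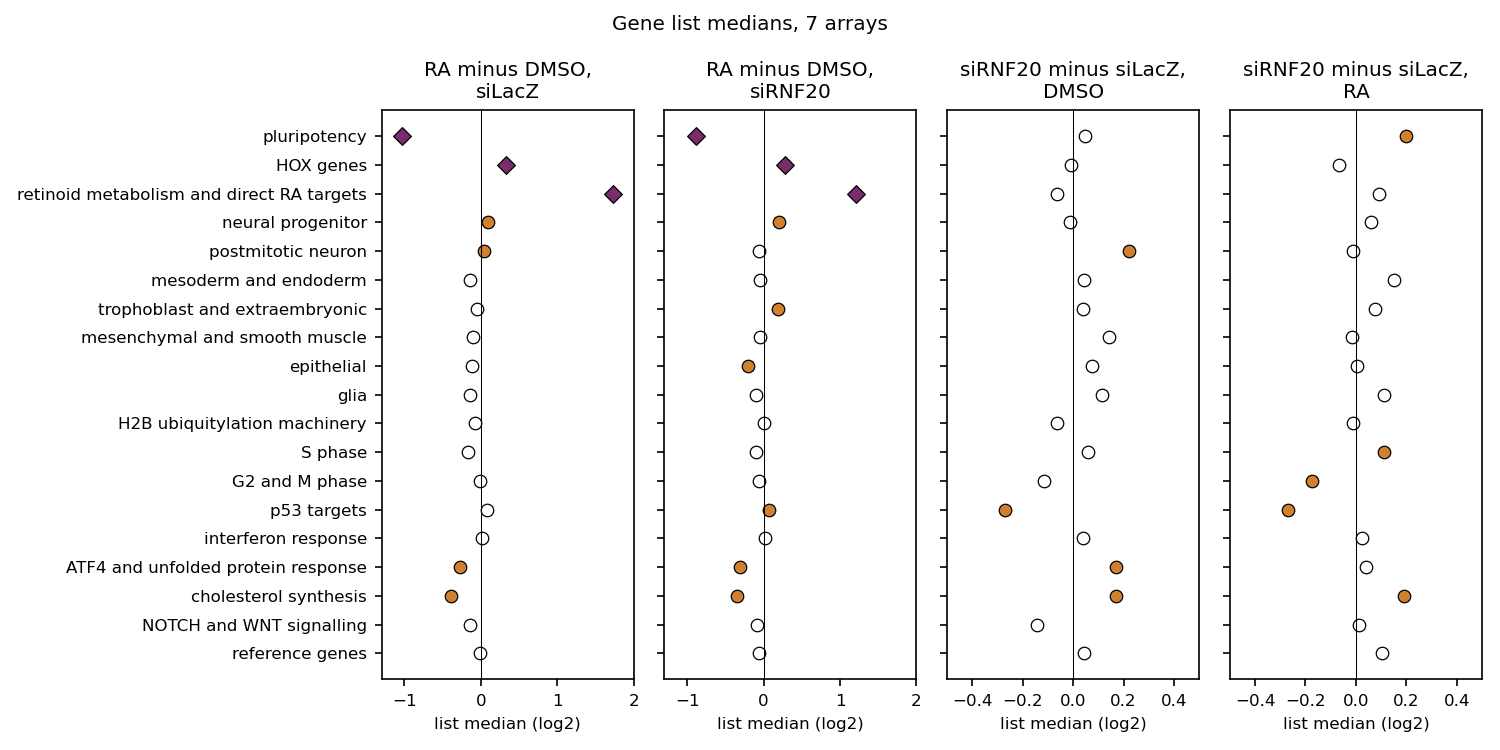
Median log2 difference of 19 gene lists (rows) in 4 comparisons (panels), from 7 arrays; filled orange points have an adjusted p below 0.05, purple diamonds also with an estimated correlation, and open points neither. Under RA the diamonds are pluripotency (-1.03 and -0.89), HOX genes (0.33 and 0.29) and the retinoid list (1.72 and 1.21).

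Whether long genes depend on RNF20 when RA induces them was the question of a last comparison. Over 336 genes that RA raised at least 2-fold in siLacZ cells, the difference between the RA responses had a Spearman rho of 0.0136 with gene length (permutation p = 0.803, adjusted p = 0.803 over 22 relations). For the 200 most raised genes with all 8 arrays rho was 0.267 (permutation p = 0.00019, adjusted p = 0.000261), over another set of genes than the 0.0136 of 7 arrays. That set was selected and measured with the GF117 RA siLacZ array included, and its rho turned sign given the rows per gene, as given in the last part. With genes selected anew each time, the sign turned from 0.0136 to -0.0314, -0.0029 and -0.0084 without the GF117 arrays of DMSO siLacZ, DMSO siRNF20 and RA siRNF20, and rho was 0.129 without the GF120 DMSO siLacZ array and 0.104 (permutation p = 0.0431) without the GF120 RA siRNF20 array. For 322 genes lowered by RA rho was -0.272 (permutation p = 1e-05, the smallest possible, adjusted p = 0.000147). In the 200 genes most raised in the GF117 siRNF20 arrays and measured in GF120, a selection added after the values were seen, rho was -0.219 (permutation p = 0.0019, adjusted p = 0.00232). Over all 18618 genes with a length, longer genes were lower with siRNF20, with rho = -0.137 in DMSO and -0.154 in RA (permutation p = 1e-04 each, the smallest possible, adjusted p = 0.000147). Within one GF number rho was -0.142 (GF117) and -0.0643 (GF120) in DMSO and -0.245 (GF120) in RA. Given the number of array rows and the level of a gene, the -0.137 in DMSO and -0.154 in RA became -0.0623 and -0.0576. From the shortest to the longest quartile of genes the median siRNF20 difference went from 0.02 to -0.06 in DMSO and from 0.07 to -0.08 in RA. Length also related to the difference of the GF117 from the GF120 array of one group, with rho = 0.172, 0.108 and 0.253 in DMSO siLacZ, DMSO siRNF20 and RA siRNF20 cells. Genes were the units of these tests and are not independent replicates. The genes raised or lowered by RA in siLacZ cells were selected on a response that is itself subtracted in the difference between responses. That choice favours low differences in raised genes and high ones in lowered genes. Whether it alone gives the rho over these genes was not tested.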

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

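All tests of explanations in this part were chosen after the result was seen. The array of GF117 RA-treated siLacZ cells had little in common with the 7 others. A mix-up among these samples is argued against by its highest gene correlation with any of them, 0.185, and another scaling by its highest rank correlation over rows, 0.612, since scaling keeps ranks. RA in siLacZ cells does not look like this on the GF120 array of the same group, whose lowest correlation with the others was 0.908. The share of the variance between rows that lies between genes, 0.204 against 0.486 or more elsewhere, is consistent with little gene-specific signal on that array. A sample from outside the series, or a fault in hybridisation, was not tested.

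The test of the difference between the RA responses marked the pluripotency list, whose median difference was 0.22 with 7 arrays, and within it OTX2 (1.62), CRIPTO (1.24), NANOG (1.06), SOX2 (0.84) and DPPA2 (-1.44), each adjusted over the list alone. A shift of all genes of that signal level is argued against, because the list's median lay at percentile 99.9 of random lists matched on level, nearly all of which lay between -0.12 and 0.15. A weaker lowering of all genes that RA lowers stays open: within GF120 the list's median, 0.17, lay at percentile 99.1 of random lists from the 200 others most lowered in the GF117 siRNF20 arrays, which favours low differences, but above 0 of 10000 from those most lowered in the GF120 siLacZ arrays, which favours high ones. Variation of the single usable RA siLacZ array stays open as well, since the adjusted p was 0.558 with an estimated correlation and 19 of 33 members were positive within GF120. A need for RNF20 in silencing pluripotency genes may be put forward as a hypothesis, which these arrays cannot separate from either.

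Longer genes were lower with siRNF20. A length relation shared by the arrays of one GF number, with rank correlations of 0.172, 0.108 and 0.253 between duplicates, cancels within a number, where siRNF20 gave -0.142 and -0.0643 in DMSO and -0.245 in RA. Length-related variation of single arrays stays open, because those 3 duplicate values range over 0.145, more than the DMSO values. The number of array rows and the signal level stay open as well, since the -0.0623 left in DMSO given both is no larger than the 0.107, 0.0628 and 0.170 between duplicates given the same. A need for RNF20 at long genes that RA raises cannot be told apart from such variation, because the rank correlation was 0.0136 over genes raised in siLacZ cells but -0.219 (permutation p = 0.0019, adjusted p = 0.00232) over 200 genes selected in the GF117 siRNF20 arrays and measured in GF120.

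GJA1 was also marked by the test of the difference between the RA responses, with 1.40 adjusted over its list alone. With all 8 arrays 10 gene lists passed that test, the reference genes among them, and 0 of the 10 passed without the GF117 RA siLacZ array, when the pluripotency list alone did. With an estimated correlation 0 lists passed (lowest adjusted p = 0.333 with an estimated correlation and 8 arrays, adjusted p = 0.558 with an estimated correlation for the pluripotency list and 7 arrays).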

How the results depend on the processing

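Leaving out each array was planned; applying the other alternatives to the 7 arrays without the GF117 RA siLacZ array, and the selections that avoid it, were chosen after seeing the data. Arrays give no depth, and signal over background limits the dimmest values. The filter on dim rows goes by the mean over arrays, so that rows dim in one group and bright in another stay in, and the size of such changes depends on how dim values are treated: SEMA3C ranged from 3.45 (offset of 16) to 5.25 with RA in siRNF20 cells, and HOXA2 from 2.38 (stricter filter) to 6.13 and SLITRK6 from 2.74 (offset) to 5.76 in siLacZ cells. With 7 arrays the pluripotency, HOX and retinoid lists kept their calls under RA in both backgrounds in all 11 alternatives run on them (highest adjusted p 0.0472). For other single genes with 7 arrays, 2414 alternatives kept direction and call, 249 ended a call (33 without the trend, 17 with a stricter filter, 15 with none and 15 with the mean over rows) and 17 gained one; for lists 221 kept them and 64 ended a call. For single genes with 8 arrays 594 kept them and 54 gained a call. Transcript length in place of gene length was not run, since no table used here gives it. Where a call ended when an array was left out, fewer arrays were in the fit; for the other changes the cause was not tested.

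Counts of genes with 8 arrays were 0, except in a fit on the 4 siRNF20 arrays, which called 549, and when an array of RA siLacZ cells was left out. Without the GF117 one 733 genes passed for RA in siLacZ cells, 734 for RA in siRNF20 cells, 2 for siRNF20 in RA and 0 for the difference between responses. Without the GF120 one the counts were 13323, 721, 12835 and 11416. With 7 arrays 456 genes passed without the intensity trend for RA in siLacZ cells (733 with it), and 317 to 970 when a further array was left out (389 without the GF120 DMSO siLacZ array); for RA in siRNF20 cells 324 to 589 passed when one was left out (371 without the GF120 DMSO siRNF20 array, 734 with all). For siRNF20 in DMSO 1 (PRDX2) passed without the GF117 DMSO siRNF20 array. For siRNF20 in RA the count was 0 with the mean over rows, with no filter or a stricter filter on dim rows, with quantile normalization and with an offset of 16, 0 to 2 when a further array was left out, 1 (CCDC190) without the trend and 48 in a fit on the groups compared.

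The GF number as a block raised the counts of 7 arrays to 1792 for RA in siLacZ cells, 1959 for RA in siRNF20 cells, 1 (RNF20) for siRNF20 in DMSO, 232 for siRNF20 in RA and 4 for the difference between responses (GJA1, LMO3, MEST and RPL9). With this block RNF20 differed by -1.94 in DMSO and -2.19 in RA, both past the threshold, and the length relation was 0.0816. Deviations of arrays with one number from their group means correlated at 0.297, 0.301 and 0.364 among the groups other than RA siLacZ and at -0.0811, -0.165 and -0.387 with that group, which holds the GF117 RA siLacZ array. The labels do not say that the number is a pairing.

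The USP44 decrease with RA in siLacZ cells ranged from -5.58 to -1.22 with 8 arrays when an array was left out; with 7 it lost its call without the trend (-1.22), with no filter on dim rows (-1.22), with the mean over rows (-1.03) and when an array was left out (-1.40 to -1.05). In siRNF20 cells it was called with 8 arrays in a fit on the 4 siRNF20 arrays (-1.11) or without an RA siLacZ array (-1.11), and lost its call with 7 arrays without the trend (-1.11), without the GF117 DMSO siRNF20 array (-0.94) and without the GF120 RA siRNF20 array (-0.80). Over all arrays left out it ranged from -1.41 to -0.80. RNF20 passed in RA in a fit on the groups compared (-2.02).

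The correlation of the RA responses with 8 arrays was 0.0636 within GF117 and 0.577 within GF120, and 0.172 to 0.699 when an array was left out; with 7 arrays it was 0.582 within GF120. With 500 genes per side the share of the response kept by raised genes was 16.95 and 51.3 in the planned selections, and with 100 genes the share kept by lowered genes was 1.05 in the selection from siRNF20 cells. The length relation with 8 arrays (0.267) turned to -0.0994 given the rows per gene, -0.0633 in genes lowered by RA, -0.0018 when selected in siLacZ GF117 and -0.0385 for siRNF20 in DMSO, and ranged from 0.0136 (without the GF117 RA siLacZ array) to 0.287 when an array was left out and the genes were selected anew. With 7 arrays (0.0136) it turned to -0.0647 over all genes, -0.0324 given the rows per gene, -0.272 in genes lowered by RA, -0.219 when selected in siRNF20 GF117, and -0.0778 and -0.0375 for siRNF20 in DMSO and in RA, and ranged from -0.0314 to 0.129 when an array was left out.

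With an estimated correlation the numbers of lists past the threshold with 8 arrays (14, 5, 2, 10 and 10 in the order of the comparisons) became 1, 1, 0, 0 and 0, and with fry 1, 1, 0, 0 and 0; for siRNF20 in DMSO the number was 0 with no filter on dim rows. Leaving out an array gave 7 to 14 for RA in siLacZ cells, 3 to 9 for RA in siRNF20 cells, 0 to 7 for siRNF20 in DMSO, 5 to 12 for siRNF20 in RA and 1 to 12 for the difference. With 7 arrays (7, 9, 4, 5 and 1) an estimated correlation gave 3, 3, 0, 0 and 0 and fry 4, 4, 0, 0 and 0; for siRNF20 in DMSO the number was 8 with the mean over rows and 2 to 6 when an array was left out, and for the difference 0 to 2 when an array was left out.

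Some values turned direction. In a fit on the 4 DMSO arrays EPCIP-AS1 stood at -1.06 with siRNF20, with 7 or 8 arrays, and HOXA5 at 0.10 with 8. Without the filter on dim rows ATP6V1G3 stood at -0.22 and TSPYL5 at 0.47 with siRNF20 in DMSO, OR5P2 at 0.39 with siRNF20 in RA, SLC46A3 at 0.10 with RA in siLacZ cells and TEKT5 at 0.0287. With a stricter filter TEKT5 stood at 0.11, CDKN1A at 0.27 in DMSO and RNF40 at -0.0904 in RA. RNF40 stood at -0.11 in RA with the mean over rows and when an array was left out ranged from -0.0721 to 0.12 in DMSO and from -0.0057 to 0.25 in RA. Without the GF120 RA siRNF20 array the G2 and M phase list turned in RA (adjusted p = 0.809; lowest 2.45e-05 when another array was left out).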
